A study of Mus musculus with 24 samples.

How the data were processed

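RNA was measured in 24 libraries of mouse intestinal stromal cells, 3 for each of 8 groups set by tissue (small intestine or colon), CD31 and an Rspo3 GFP reporter. Per the labels' protocols, the cells came from mice of 8 to 12 weeks on a C57Bl6 background, RNA was purified with a Qiagen RNeasy kit and libraries were made with SMART-Seq v4 chemistry, a full-length method that does not mark strand. Per the submitters' processing notes, Salmon 1.3.0 and R 4.0.1 were used with genome build mm10. The transcript annotation release, the filters and the way transcripts were summed to genes are not given in the sources used here. The deposited estimated counts are whole numbers per gene and library, not scaled to a common total, so that no further rounding was needed. The deposited log2 values are log2(TPM + 1), since the back-transformed values add up to the TPM total in every library. Of these values, 402 were above 0 where the count was 0.

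Columns were matched to groups through the tissue, CD31 and reporter signs in their names, which carry no replicate number of the labels. Library numbers 1 to 3 in a group therefore follow column order and were not used as pairs. Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, in which 54096 of 54418 gene IDs (99.4%) were found. The others stayed in the tests under their IDs and held at most 0.068% of the counts of a library. Within each group, all pairs of libraries were compared by correlation and by a chi-square test over genes with a summed count of at least 20, and all were kept as separate replicates.

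The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM scaling and filterByExpr (minimum count 10, minimum total 15), which left 19050 genes. All libraries entered 1 model with 1 mean per group and no covariate. The common biological coefficient of variation was 0.429 and the prior degrees of freedom 3.50. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were Rspo3+ against Rspo3- within CD31+ and within CD31- cells of each tissue, CD31+ against CD31- among Rspo3+ cells of each tissue, and colon against small intestine within each Rspo3+ fraction. Interaction contrasts then tested whether the Rspo3 difference differed between the tissues, and the genes higher in Rspo3+ cells in all 4 Rspo3 comparisons, which share no library, were counted beside the overlap expected of the 2 CD31 gates, an expectation chosen afterwards in place of that of 4 independent lists. Log2 fold changes are edgeR's, with SE from the fitted coefficient and its F statistic.

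In total 34 gene lists were fixed from textbook knowledge. They covered lymphatic, blood and pan-endothelial genes, pan-fibroblast, Pdgfra-low Grem1+ and Pdgfra-high fibroblast genes, smooth muscle, pericytes, enteric glia and neurons, interstitial cells of Cajal, mesothelium, epithelium, immune and erythroid cells. Others held R-spondins, Wnt ligands, secreted Wnt antagonists, BMP ligands and antagonists, epithelial and vascular growth factors, chemokines and cytokines, Hedgehog targets, the Notch pathway, retinoic acid metabolism and prostaglandin synthesis. The rest were basement membrane, interferon response, MHC class II, immediate early and heat shock, cell cycle, and anterior and posterior Hox genes. Members that rose or fell were counted over all genes tested and adjusted over the list alone. Lists were tested with camera (limma 3.58.1, voom values) at a preset correlation of 0.01 and at an estimated correlation, adjusted over the lists of a comparison.

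Genes were named by a rule. Pecam1, Rspo3 and Grem1 were taken in every comparison. For each pairwise comparison, the 5 largest rises and the 5 largest falls were taken among genes that passed, had at least 10 CPM in the higher group, showed no overlap between the libraries of both groups and had a symbol other than a predicted-gene name. From each list described came the 3 members with the smallest adjusted p and, where members went the other way, the 1 with the smallest adjusted p among these. Interactions gave the 5 genes with the smallest adjusted p, and the genes shared by all 4 Rspo3 comparisons the 20 with the largest minimum fold change and at least 10 CPM in each Rspo3+ group. Some genes that the rule selected are not reported here. The tests, the lists, the rule and the alternatives were fixed before the data were examined, apart from choices named as made afterwards. Where all libraries of a group were at 0, a fold was computed against a floor of 3 counts over the group. Where they held 1 to 3 counts in sum, the ratio has a 95% counting interval.

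Library totals set the precision. The test was run on simulated data with the means and totals of the small intestinal CD31+ comparison (17234 genes, 200 changed). It recovered 34.0% of genes changed 2-fold and 73.0% of genes changed 4-fold, with 1.83% false among 109 calls. Alternatives were DESeq2 size factors in edgeR, no filter on low counts, DESeq2's Wald test (1.42.0), limma voom with sample weights, limma-trend on the deposited log2 TPM values, a fit of only the libraries compared, each library left out in turn and, for the shared genes, a threshold of 0.01. Leaving out a pair of colonic libraries with RNA of other cell types was added after the data were seen. Where leaving out a library left 2 in a group, the spread still came from all groups. Planned fits with the replicate number as a block were not run.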

Results

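Gene expression was measured by RNA sequencing (SMART-Seq v4 libraries) in mouse stromal cells from the small intestine and the colon that lacked Epcam, an epithelial surface protein, and CD45, a leukocyte surface protein. The cells were divided by CD31, an endothelial surface protein encoded by Pecam1, and by a GFP transgene reporting Rspo3, the gene for R-spondin 3, a secreted enhancer of Wnt signaling. The 24 libraries formed 8 groups of 3, 1 for each combination of tissue, CD31 and Rspo3 reporter. Estimated counts summed to 8462041 to 29214487 per library (median 17881736), and 19050 of 54418 genes had enough counts to be tested. Levels are given below in CPM, counts scaled to a common library total with TMM factors, as mean ± SD of 3 libraries unless stated otherwise. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Correlations of log2 CPM between libraries of 1 group ran from 0.895 to 0.967, and every pair differed by more than sampling noise (lowest chi-square per degree of freedom 27.2).

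Pecam1 (ENSMUSG00000020717, chromosome 11, 106654217 to 106750628 on GRCm38) stood at 13.3 ± 2.80 CPM in small intestinal CD31- Rspo3- and 14.9 ± 4.28 CPM in CD31- Rspo3+ cells. It was at 1133 ± 83.6 CPM in CD31+ Rspo3- and 421 ± 68.3 CPM in CD31+ Rspo3+ cells. In the colon the same 4 groups held 10.3 ± 2.22, 25.3 ± 16.4, 1338 ± 240.3 and 640.3 ± 46.5 CPM. Rspo3 (ENSMUSG00000019880, chromosome 10, 29452416 to 29535867) was at 311 ± 32.8 CPM in CD31- and 385 ± 75.1 CPM in CD31+ reporter-positive cells of the small intestine. The reporter-negative cells held 15.3 ± 1.94 and 20.3 ± 4.51 CPM. Colonic reporter-positive cells held 213 ± 66.4 CPM of Rspo3 in the CD31- and 373 ± 30.9 CPM in the CD31+ fraction, against 14.2 ± 1.73 and 14.1 ± 2.56 CPM. Grem1 (ENSMUSG00000074934, chromosome 2, 113746164 to 113758646), a secreted BMP antagonist named in the study's title, reached 884 ± 119 CPM in small intestinal and 744 ± 226 CPM in colonic CD31- Rspo3+ cells. In CD31- Rspo3- cells it was at 47.7 ± 8.00 and 62.3 ± 19.0 CPM, and in CD31+ Rspo3+ cells at 9.31 ± 3.89 and 18.8 ± 15.5 CPM. Colonic CD31+ Rspo3- library 3 held 28.8 CPM of Grem1 and 2467 CPM of the fibroblast gene Dcn. The other libraries of that group held 421 and 471 CPM of Dcn. Dcn, and the markers Epcam, Ptprc, Igkc and H2-Ab1 of other cell types given below, were chosen after their values were seen.

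**Figure D1:**
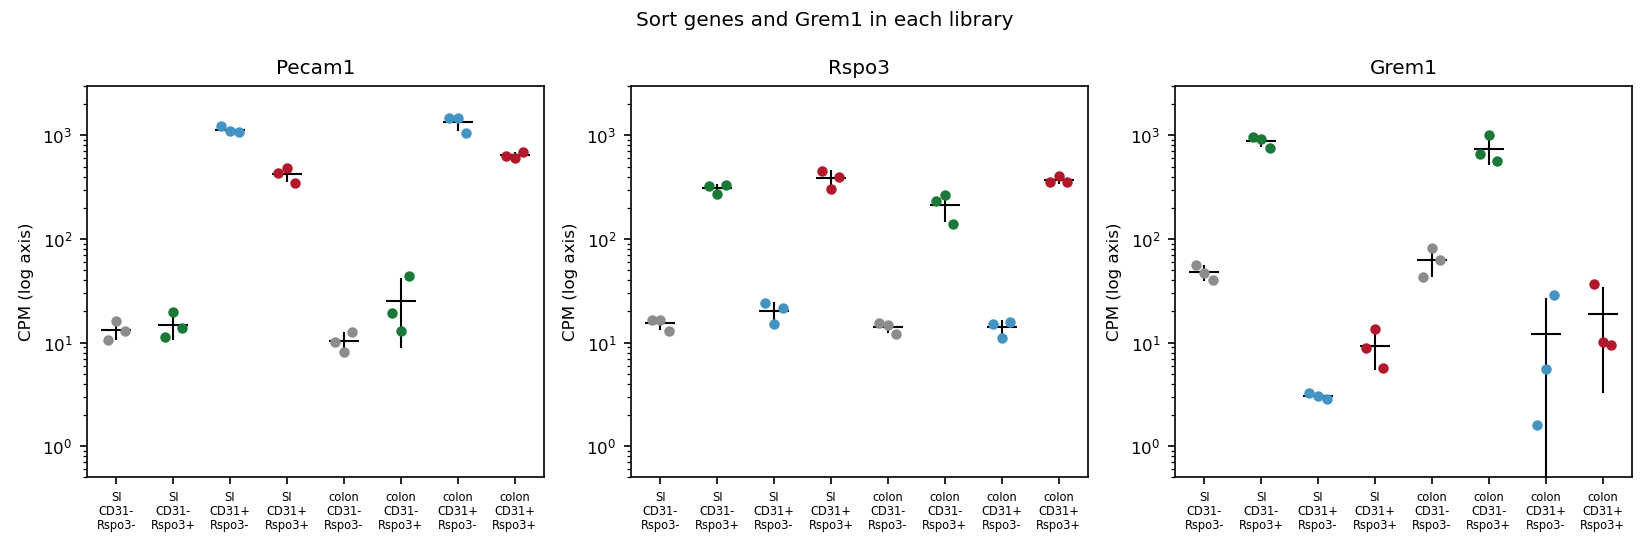
Levels of Pecam1, Rspo3 and Grem1 (CPM, log axis) in each library of the 8 groups named on the horizontal axis (SI, small intestine); each point is 1 library, horizontal dashes are group means and vertical bars their SD, clipped at the axis where the SD exceeds the mean. Rspo3 lies between 139 and 449.9 CPM in the 12 reporter-positive libraries and between 11.1 and 24.1 CPM in the others.

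The first question was which genes marked the Rspo3+ fraction of CD31+ cells. Of the lymphatic endothelial list, 12 of 15 rose in the small intestine and 14 of 15 in the colon (12 and 14 adjusted over the list alone). For lymphatic genes camera gave adjusted p = 5.19e-15 and 1.06e-21, or 0.0181 and 0.00628 with an estimated correlation. Of the blood endothelial list, 17 of 20 fell in the small intestine and 17 of 20 in the colon (18 and 17 adjusted over the list alone). For blood endothelial genes camera gave adjusted p = 4.27e-23 and 1.32e-20, or 0.018 and 0.0173 with an estimated correlation. In the small intestine Nrp2, a co-receptor for VEGF-C, rose from 149 ± 26.0 to 1029 ± 204 CPM (log2 fold change 2.79 ± 0.28 SE, adjusted p = 3.96e-07). Fgl2, a secreted fibrinogen-like protein, rose from 1148 ± 316 to 4585 ± 477 CPM (log2 fold change 2.00 ± 0.22 SE, adjusted p = 1.4e-06). Colonic Ccl21a, a chemokine that guides leukocytes into lymphatic vessels and shares reads with near-identical copies, rose from 1244 ± 123 to 26946 ± 5827 CPM (log2 fold change 4.44 ± 0.40 SE, adjusted p = 1.11e-07). Of the blood endothelial genes, Nrp1, a co-receptor for VEGF-A, fell from 714 ± 109 to 16.9 ± 6.04 CPM in the small intestine and from 929.6 ± 149 to 33.5 ± 17.1 CPM in the colon (adjusted p = 3.4e-09 and 9.59e-09).

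Aqp1, a water channel on the blood endothelial list, rose from 511 ± 72.2 to 2073 ± 654 CPM in the small intestine (adjusted p = 0.00592). Of the pan-endothelial list, 3 of 16 fell in the small intestine (3 adjusted over the list alone, camera adjusted p = 0.677, and adjusted p = 0.926 with an estimated correlation). The list's median there was 0.02 in log2 and turned to -0.01 with DESeq2 size factors. The junction gene Esam fell from 1083 ± 76.1 to 20.6 ± 3.68 CPM there and from 1026 ± 190.3 to 53.1 ± 12.3 CPM in the colon. Tek, the angiopoietin receptor, fell from 568 ± 72.3 to 228 ± 15.6 CPM and from 663 ± 123 to 320.4 ± 22.6 CPM. Of the smooth muscle list, 9 of 12 fell in the small intestine and 10 of 12 in the colon (10 and 10 adjusted over the list alone). For smooth muscle genes camera gave adjusted p = 0.000463 and 0.000398, or 0.527 and 0.495 with an estimated correlation. Tagln, an actin-binding gene of smooth muscle, fell from 158 ± 51.4 to 25.7 ± 9.37 CPM and from 146 ± 56.0 to 35.8 ± 7.56 CPM. Of the pericyte list, 7 of 10 fell in the small intestine and 8 of 10 in the colon (7 and 9 adjusted over the list alone). For pericyte genes camera gave adjusted p = 0.0332 and 2.01e-05, or 0.574 and 0.185 with an estimated correlation. Rgs5, a pericyte regulator of G-protein signaling, fell from 241 ± 21.4 to 13.7 ± 6.69 CPM and from 441 ± 128 to 18.2 ± 6.11 CPM. Kcnj8, a potassium channel subunit on the same list, rose from 22.8 ± 5.28 to 338 ± 24.3 CPM in the small intestine.

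Of the Notch pathway list, 8 of 13 fell in the small intestine and 6 of 13 in the colon (8 and 8 adjusted over the list alone). For Notch genes camera gave adjusted p = 8.71e-05 and 0.000398, or 0.147 and 0.205 with an estimated correlation. The Notch ligand Jag2 fell from 133 ± 22.5 to 7.16 ± 1.09 CPM and from 123 ± 44.7 to 5.79 ± 3.42 CPM. Notch2, a receptor, rose from 4.55 ± 1.90 to 20.5 ± 8.46 CPM in the small intestine. Wnt2, a secreted Wnt ligand, rose from 32.2 ± 11.6 to 278 ± 44.1 CPM in the small intestine and from 2.44 ± 1.61 to 15.7 ± 3.28 CPM in the colon (adjusted p = 8.84e-05 and 0.000525). Among vascular growth factors of the small intestine, Vegfc fell from 108 ± 10.5 to 2.40 ± 1.73 CPM, Kitl fell from 121 ± 28.8 to 3.27 ± 1.29 CPM and Pgf rose from 15.6 ± 1.29 to 189 ± 61.7 CPM. Il33, a nuclear alarmin cytokine, rose from 227 ± 93.4 to 1206 ± 361 CPM in the small intestine. Il7, a lymphocyte survival cytokine, rose from 15.4 ± 3.46 to 242 ± 42.4 CPM in the colon. With DESeq2 size factors, 3 of 18 chemokines and cytokines rose and 5 fell in the small intestine, and 3 and 7 in the colon. Of the interferon response list, 9 of 16 rose in the small intestine (10 adjusted over the list alone, camera adjusted p = 4.35e-05, and adjusted p = 0.271 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose from 20.1 ± 6.62 to 153 ± 29.8 CPM. In the colon, 5 rose, 7 fell and 4 did not pass the test (5 and 7 adjusted over the list alone, camera adjusted p = 0.592, and adjusted p = 0.919 with an estimated correlation). Immediate early and heat shock genes respond to cell handling as well as to signals in tissue. In the colon 13 of 16 fell (13 adjusted over the list alone, camera adjusted p = 1.07e-11, and adjusted p = 0.0418 with an estimated correlation), with Fos from 8623 ± 625 to 2229 ± 514 CPM. In the small intestine, 3 rose, 3 fell and 10 did not pass the test (3 and 3 adjusted over the list alone, camera adjusted p = 0.677, and adjusted p = 0.926 with an estimated correlation).

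Among genes with at least 10 CPM in the higher group, the largest rises in small intestinal CD31+ Rspo3+ cells were Nefl at least 203-fold, Atp12a 145-fold, Pld5 99.6-fold, Acod1 61.8-fold and Prf1 44.8-fold. The largest falls were Gna14 at least 172-fold, Spp1 at least 160.5-fold, Lhx6 804-fold with a counting interval of 222 to 6645, Endou 668-fold with a counting interval of 185 to 5523 and C1qtnf9 599-fold. In the colon the largest rises were Fam205a4 at least 340.3-fold, Pld5 69.2-fold, Slc22a3 45.4-fold, Alox12e 42.2-fold and Apba2 34.5-fold. Colonic falls were led by Epha4 157-fold, Slc28a2 84.3-fold, Fam167b 82.4-fold, Efr3b 75.8-fold and Enpp6 71.7-fold. Fam205a4 has near-identical copies, so its level is uncertain. Acod1 was 32.4-fold without Rspo3+ library 2. Spp1 lost its call without Rspo3+ library 1, 2 or 3 (adjusted p = 0.0807, 0.0692 and 0.0597), with 0.000301 to 0.0807 over its alternatives. Fam205a4 lost its call without Rspo3- library 1, 2 or 3 (adjusted p = 0.0565, 0.0537 and 0.0513), with 1.14e-18 to 0.0565 over its alternatives. Folds marked at least, here and below, were taken against a floor of 3 counts over the 3 libraries of the group at 0, and floors and intervals cover counting error only.

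With edgeR's quasi-likelihood test, 3820 genes differed in the small intestine (1758 higher and 2062 lower in Rspo3+ cells), and 4405 in the colon (1814 higher and 2591 lower). Both tissues shared 964 higher and 1422 lower genes, where independent lists would share 167 and 280.4. Another 56 genes went opposite ways. Pecam1 fell to the levels given above in the small intestine and the colon (adjusted p = 0.00256 and 0.0181). Colonic Pecam1 lost its call without Rspo3+ library 1, 2 or 3 (adjusted p = 0.0681, 0.0635 and 0.0522) or Rspo3- library 1 or 2 (adjusted p = 0.0731 and 0.0751), with 0.000119 to 0.0751 over its alternatives. Grem1 did not pass the test in either tissue (adjusted p = 0.116 and 0.526). Over its alternatives the small intestinal value ran from 0.0358 to 0.289, passing with DESeq2 and with only the compared libraries. Without Rspo3- library 3, colonic Grem1 passed the test (adjusted p = 0.00433, with 0.00433 to 0.888 over its alternatives).

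The next comparison asked which genes marked the Rspo3+ fraction of CD31- stroma. Of a list of Pdgfra-low, Grem1+ fibroblasts, which lie near the crypt base, 11 of 16 rose in the small intestine and 7 of 16 in the colon (14 and 10 adjusted over the list alone). For Pdgfra-low fibroblast genes camera gave adjusted p = 6.18e-06 and 4.66e-11, or 0.286 and 0.0493 with an estimated correlation. Of the Pdgfra-high subepithelial fibroblast list, 9 of 14 fell in the small intestine and 9 of 14 in the colon (11 and 12 adjusted over the list alone). For Pdgfra-high fibroblast genes camera gave adjusted p = 0.00156 and 9.59e-14, or 0.473 and 0.0493 with an estimated correlation. Grem1 rose to the levels given above in the small intestine (log2 fold change 4.21 ± 0.72 SE, adjusted p = 0.000169). In the colon it rose by 3.58 ± 0.69 SE in log2 (adjusted p = 0.00242). Cd34, a surface sialomucin of stromal progenitors, rose from 330.2 ± 55.9 to 1578 ± 104 CPM and from 481 ± 42.6 to 1493 ± 397 CPM. Bmp5, a BMP ligand of the subepithelial fibroblasts, fell from 97.2 ± 19.3 to 23.9 ± 4.94 CPM and from 359 ± 57.1 to 28.2 ± 9.32 CPM. Dpp4, a peptidase on the Pdgfra-low list, fell from 339.8 ± 95.0 to 8.89 ± 2.87 CPM in the small intestine (adjusted p = 1.68e-06).

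Of the R-spondins, which include the reporter's own gene, 3 of 3 rose in the small intestine and 2 of 3 in the colon (3 and 2 adjusted over the list alone). For the R-spondins camera gave adjusted p = 0.000298 and 8.94e-05, or 0.027 and 0.0209 with an estimated correlation. Rspo2 rose from 5.13 ± 1.84 to 66.8 ± 3.64 CPM and from 0.668 ± 0.363 to 6.69 ± 1.65 CPM. In the colon Rspo2 lost its call without Rspo3+ library 1 or 2 (adjusted p = 0.0825 and 0.0948) or Rspo3- library 1, 2 or 3 (adjusted p = 0.0846, 0.157 and 0.143), with 0.00131 to 0.157 over its alternatives. Of the pan-fibroblast list, 10 of 14 rose in the small intestine and 1 of 14 in the colon (11 and 4 adjusted over the list alone). For pan-fibroblast genes camera gave adjusted p = 1.06e-05 and 0.00306, or 0.391 and 0.438 with an estimated correlation. The colonic count was 3 without Rspo3+ library 3. Of the BMP antagonists, 5 of 11 rose in the small intestine (5 adjusted over the list alone, camera adjusted p = 0.00206, and adjusted p = 0.387 with an estimated correlation). With DESeq2 size factors, 3 of 11 Wnt ligands rose and 1 fell in the small intestine, against 0 and 2 in the colon. Wnt4 fell from 35.3 ± 5.51 to 8.02 ± 4.23 CPM and from 75.2 ± 21.5 to 4.29 ± 1.43 CPM. The Wnt antagonist Sfrp5 fell from 7.79 ± 1.77 to 0.381 ± 0.353 CPM and from 22.0 ± 8.81 to 0.909 ± 0.531 CPM.

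Markers of other cell types moved with the reporter in CD31- cells. Epcam stood at 594, 686 and 1069 CPM in the small intestinal Rspo3- libraries, against 6.62, 21.8 and 23.6 CPM in Rspo3+ libraries. Mitochondrial transcripts took 2.67 to 4.82% of the counts in the small intestinal Rspo3- and 0.69 to 1.27% in the Rspo3+ libraries, against 1.36 to 1.97% and 0.698 to 1.44% in the colon. Of the epithelial list, 11 of 16 fell in the small intestine and 2 of 16 in the colon (12 and 3 adjusted over the list alone). For epithelial genes camera gave adjusted p = 7.14e-06 and 0.00116, or 0.387 and 0.385 with an estimated correlation. The colonic epithelial count was 10 without Rspo3+ library 3, 1 without Rspo3- library 1, and 0 without Rspo3+ library 1 or 2 (3 at an unadjusted p under 0.05 in edgeR each time). The brush border gene Vil1 fell from 795 ± 358 to 12.2 ± 4.98 CPM in the small intestine. Of the MHC class II list, 7 of 7 fell in the small intestine (7 adjusted over the list alone, camera adjusted p = 0.00046, and adjusted p = 0.404 with an estimated correlation), and 4 without Rspo3+ library 1. Of the enteric glia list, 9 of 9 fell in the small intestine and 8 of 9 in the colon (9 and 9 adjusted over the list alone). For glial genes camera gave adjusted p = 3.77e-06 and 3.64e-11, or 0.156 and 0.0209 with an estimated correlation. The colonic glia count was 4 without Rspo3+ library 1 and 5 without Rspo3+ library 2. Of the smooth muscle list, 11 of 12 fell in the colon (12 adjusted over the list alone, camera adjusted p = 1.86e-18, and adjusted p = 0.0209 with an estimated correlation). The myosin kinase gene Mylk fell from 399.8 ± 5.81 to 56.9 ± 6.86 CPM. In the small intestine Mylk was at 218 ± 30.3 against 312 ± 37.6 CPM (adjusted p = 0.0549), and its fall passed under 7 alternatives, among them DESeq2 and limma voom (adjusted p = 0.00636 and 0.00831, with 0.00636 to 0.151 over all). Of the mesothelial list, 6 of 7 fell in the small intestine (6 adjusted over the list alone, camera adjusted p = 0.000331, and adjusted p = 0.027 with an estimated correlation).

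Some endothelial genes were higher in the CD31- Rspo3+ fraction as well. Of the lymphatic list, 12 of 15 rose in the small intestine and 7 of 15 in the colon (12 and 8 adjusted over the list alone). For lymphatic genes camera gave adjusted p = 0.000148 and 0.00124, or 0.286 and 0.22 with an estimated correlation. Of the pan-endothelial list, 11 of 16 rose in the small intestine and 12 of 16 in the colon (11 and 12 adjusted over the list alone). For pan-endothelial genes camera gave adjusted p = 0.00215 and 6.41e-06, or 0.418 and 0.131 with an estimated correlation. Mmrn1, a lymphatic extracellular matrix protein, rose from 1.62 ± 0.786 to 128 ± 98.9 CPM and from 0.627 ± 0.543 to 23.4 ± 5.47 CPM. CD31+ Rspo3+ cells of the same tissues held 14152 ± 2130.2 and 9922 ± 1278 CPM of it. Of the immediate early and heat shock list, 13 of 16 rose in the small intestine and 10 of 16 in the colon (14 and 12 adjusted over the list alone). For immediate early genes camera gave adjusted p = 9.11e-11 and 1.07e-10, or 0.0485 and 0.0267 with an estimated correlation. Egr1 was at 14145 ± 1708 against 3425 ± 366 CPM in the small intestine and Atf3 at 2229 ± 535 against 1007 ± 85.7 CPM in the colon. The colonic count was 6 without Rspo3- library 1 and 5 without Rspo3+ library 1. Of the immune list, 10 of 14 rose in the colon (14 adjusted over the list alone, camera adjusted p = 2.32e-05, and adjusted p = 0.305 with an estimated correlation). That count was 0 without Rspo3+ library 3 (1 at an unadjusted p under 0.05 in edgeR), 3 without Rspo3- library 1 and 2 without Rspo3- library 2. Library 3 of the colonic Rspo3+ group held 72.8 CPM of Ptprc, the CD45 gene, and 22999 CPM of the immunoglobulin gene Igkc. The other libraries of that group held 3.71 and 2.75 CPM of Ptprc and 1124 and 934 CPM of Igkc.

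The largest rises in small intestinal CD31- Rspo3+ cells were Igkv8-27 666-fold with a counting interval of 228 to 3234, Adgrg3 123-fold, Il31ra 106-fold, Epyc 104-fold and Mmrn1 69.0-fold. Falls there were led by Pof1b 939.9-fold with a counting interval of 168 to 37165, Slc5a8 375-fold with a counting interval of 104 to 3105, Ugt2b36 367-fold with a counting interval of 101 to 3039, Trim40 241-fold with a counting interval of 82.1 to 1171 and Clec2e 194-fold. In colonic CD31- cells the largest rises were Igkv2-137 402-fold, Mmrn1 36.8-fold, Cyth4 33.3-fold, Il21r 36.0-fold and Brinp3 22.9-fold. Colonic falls were led by Foxl1 70.3-fold, Wif1 42.8-fold, Actc1 45.0-fold, Dnaic1 36.6-fold and Pde1c 36.9-fold. Small intestinal Mmrn1 was 40.4-fold without Rspo3+ library 2, and without Rspo3+ library 3 colonic Igkv2-137 was 76.4-fold, Cyth4 3.87-fold and Il21r 3.26-fold. Foxl1 encodes a transcription factor of subepithelial fibroblasts and Wif1 a secreted Wnt inhibitor. Immunoglobulin variable genes and Ugt2b36 belong to families of near-identical genes, so their levels are uncertain. In all, 5796 genes differed in the small intestine (3064 higher and 2732 lower in Rspo3+ cells, edgeR) and 1741 in the colon (914 higher and 827 lower). The small intestinal balance turned under 10 of 12 alternatives, to 2329 higher and 3054 lower with DESeq2 size factors and 1701 and 2590 or 1686 and 2670 without Rspo3+ library 2 or 3. The colonic one turned under 7 of 13, to 439 and 2867 with limma-trend on log2 TPM and 519 and 693 or 504 and 599 without Rspo3- library 2 or 3. Both tissues shared 574 higher and 434 lower genes, against 147 and 119 for independent lists. The colonic count was 1086 without Rspo3+ library 1 and 1103 without Rspo3- library 3. Pecam1 did not pass the test in the small intestine (adjusted p = 0.754) and rose in the colon (adjusted p = 0.0147). In the small intestine Igkv8-27 lost its call without Rspo3+ library 1, 2 or 3 (adjusted p = 0.0696, 0.0556 and 0.0724) or Rspo3- library 1, 2 or 3 (adjusted p = 0.125, 0.111 and 0.106), with 0.000178 to 0.125 over its alternatives. In the colon 5 of these calls were lost on leaving out 1 library. Cyth4 lost its call without Rspo3+ library 3 (adjusted p = 0.184) or Rspo3- library 2 (adjusted p = 0.0571), with 2.07e-05 to 0.196 over its alternatives. Foxl1 lost its call without Rspo3+ library 1 or 2 (adjusted p = 0.0876 and 0.087) or Rspo3- library 3 (adjusted p = 0.0558), with 1.92e-06 to 0.0876 over its alternatives. Igkv2-137 lost its call without Rspo3+ library 1 or 3 (adjusted p = 0.0516 and 0.087) or Rspo3- library 1, 2 or 3 (adjusted p = 0.0878, 0.122 and 0.131), with 0.0021 to 0.517 over its alternatives. Il21r lost its call without Rspo3+ library 3 (adjusted p = 0.451) or Rspo3- library 1, 2 or 3 (adjusted p = 0.0731, 0.0907 and 0.0847), with 0.0005 to 0.459 over its alternatives. Pecam1 lost its call without Rspo3+ library 3 (adjusted p = 0.117) or Rspo3- library 1 or 2 (adjusted p = 0.0521 and 0.0773), with 0.00152 to 0.281 over its alternatives.

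**Figure D2:**
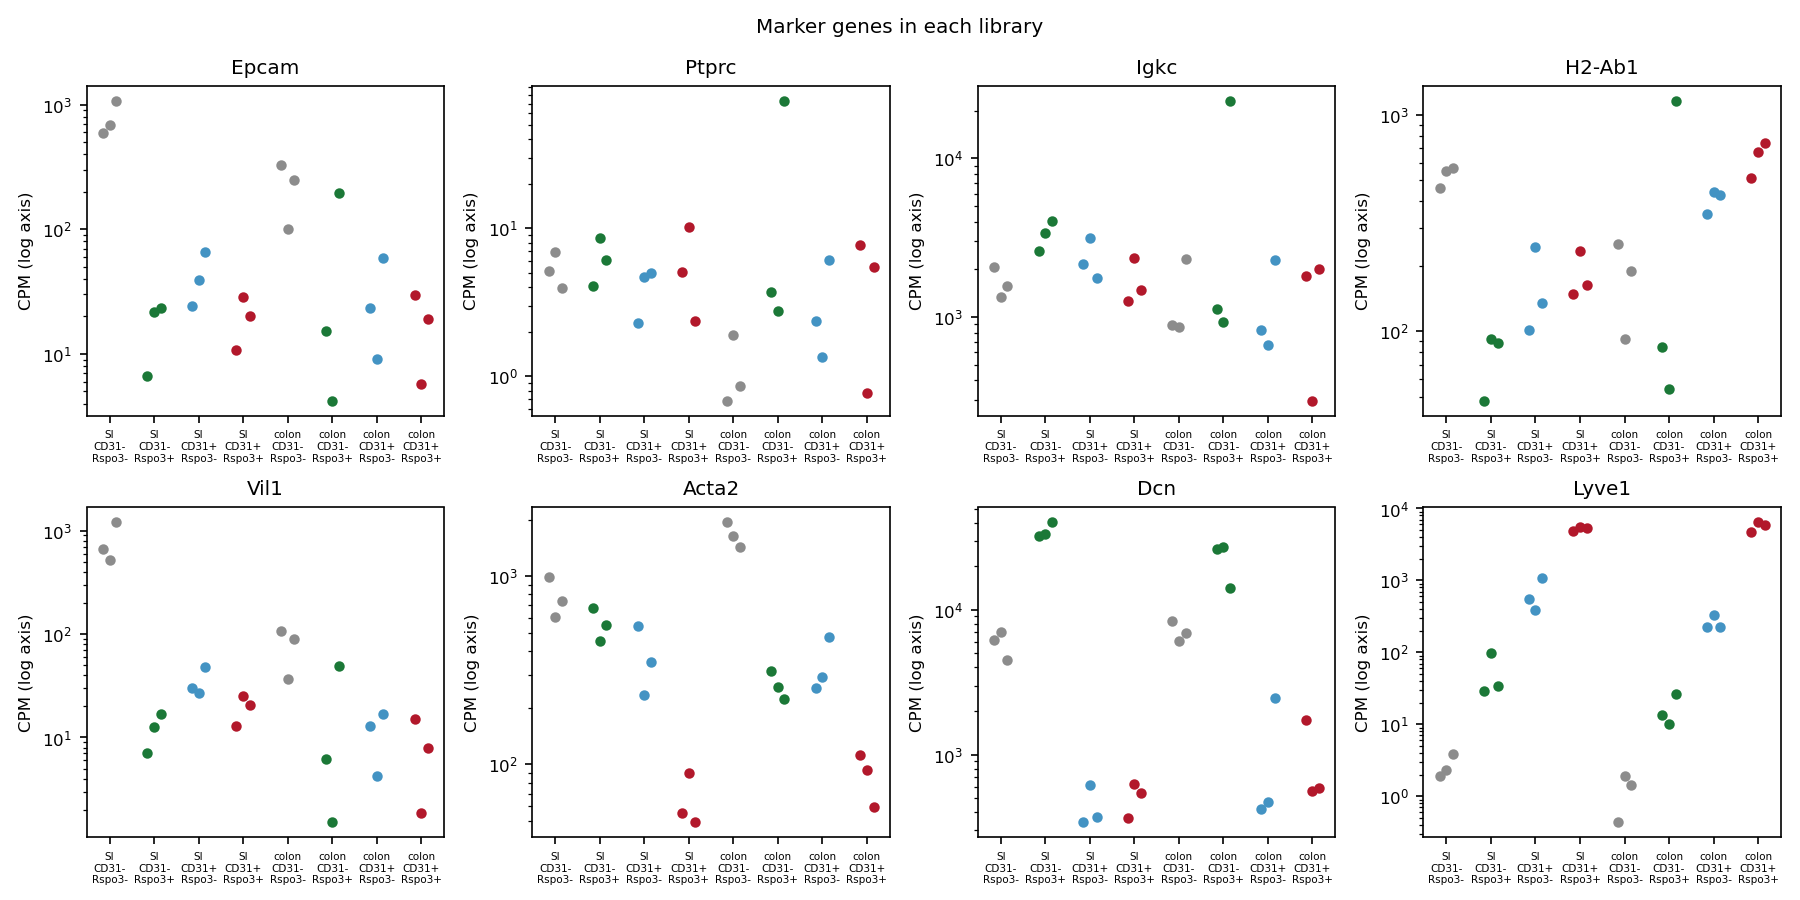
Levels (CPM, log axis) of 8 marker genes in each library of the 8 groups on the horizontal axis (SI, small intestine; 1 point per library). Epcam is highest in the small intestinal CD31- Rspo3- libraries (594 to 1069 CPM), and 1 colonic CD31- Rspo3+ library stands apart from the others of its group in Ptprc (72.8 CPM), Igkc (22999 CPM) and H2-Ab1 (1157 CPM).

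Next, the CD31+ and the CD31- fraction of Rspo3+ cells were set against each other. Rspo3 itself was at 385 ± 75.1 against 311 ± 32.8 CPM in the small intestine (adjusted p = 0.299) and 373 ± 30.9 against 213 ± 66.4 CPM in the colon (adjusted p = 0.00698). Rspo1 fell from 29.7 ± 3.61 to 0.635 ± 0.571 CPM in the small intestine and from 11.8 ± 2.10 to 0.297 ± 0.264 CPM in the colon, from CD31- to CD31+ cells. Rspo2 fell from 66.8 ± 3.64 to 1.59 ± 1.39 CPM in the small intestine. Prox1, the transcription factor of lymphatic identity, rose from 5.75 ± 4.23 to 570.0 ± 146 CPM and from 2.21 ± 0.552 to 378 ± 26.0 CPM. Ccl21a rose from 195 ± 81.7 to 9182 ± 814 CPM and from 107 ± 28.0 to 26946 ± 5827 CPM (adjusted p = 3.33e-09 and 2.88e-10).

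Of the lymphatic list, 15 of 15 rose in the small intestine and 15 of 15 in the colon (15 and 15 adjusted over the list alone). For lymphatic genes camera gave adjusted p = 1.45e-15 and 1.2e-16, or 0.0162 and 0.0123 with an estimated correlation. Of the pan-endothelial list, 16 of 16 rose in the small intestine and 15 of 16 in the colon (16 and 15 adjusted over the list alone). For pan-endothelial genes camera gave adjusted p = 1.77e-18 and 7.62e-19, or 0.0162 and 0.0123 with an estimated correlation. Tie1, an endothelial receptor kinase, rose from 10.5 ± 3.73 to 845 ± 64.2 CPM and from 11.2 ± 6.49 to 704 ± 53.2 CPM. Of the pan-fibroblast list, 14 of 14 fell in the small intestine and 14 of 14 in the colon (14 and 14 adjusted over the list alone). For pan-fibroblast genes camera gave adjusted p = 6.46e-14 and 2.79e-13, or 0.105 and 0.0864 with an estimated correlation. Fbln1, an extracellular matrix protein, fell from 5968 ± 441 to 75.8 ± 17.6 CPM and from 2196 ± 637 to 97.0 ± 13.0 CPM. Of the BMP antagonists, 10 of 11 fell in the small intestine and 8 of 11 in the colon (11 and 9 adjusted over the list alone). For BMP antagonists camera gave adjusted p = 5.31e-06 and 0.000119, or 0.11 and 0.144 with an estimated correlation. Bmp4, a BMP ligand, fell from 201 ± 18.0 to 9.58 ± 4.72 CPM and from 306 ± 81.5 to 30.2 ± 4.28 CPM. Of the epithelial growth factor list, 8 of 13 fell in the small intestine and 7 of 13 in the colon (8 and 7 adjusted over the list alone). For epithelial growth factors camera gave adjusted p = 0.0178 and 0.0198, or 0.221 and 0.201 with an estimated correlation. Fgf7, a growth factor for epithelium, fell from 75.1 ± 9.34 to 1.22 ± 1.03 CPM and from 68.6 ± 29.4 to 3.19 ± 2.13 CPM. Igf1 fell from 291 ± 4.10 to 8.63 ± 3.17 CPM and from 248 ± 79.4 to 16.0 ± 9.12 CPM. Wnt2 rose from 2.95 ± 1.38 to 278 ± 44.1 CPM in the small intestine, and Wnt9b from 0.0325 ± 0.0563 to 5.90 ± 2.94 CPM in the colon.

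Of the Hedgehog pathway targets, 9 of 9 fell in the small intestine and 9 of 9 in the colon (9 and 9 adjusted over the list alone). For Hedgehog targets camera gave adjusted p = 1.1e-05 and 1.33e-06, or 0.149 and 0.113 with an estimated correlation. Gli1, a Hedgehog transcription factor, fell from 19.7 ± 4.94 to 1.16 ± 0.836 CPM and from 34.6 ± 7.11 to 2.00 ± 0.984 CPM. Of the Notch pathway list, 9 of 13 rose in the small intestine and 7 of 13 in the colon (9 and 9 adjusted over the list alone). For Notch genes camera gave adjusted p = 0.000678 and 0.000242, or 0.149 and 0.113 with an estimated correlation. The ligand Dll4 rose from 3.81 ± 1.49 to 230.5 ± 30.8 CPM and from 6.89 ± 5.90 to 211 ± 27.7 CPM. Of the interferon response list, 13 of 16 rose in the small intestine and 9 of 16 in the colon (13 and 9 adjusted over the list alone). For interferon genes camera gave adjusted p = 3.76e-10 and 9.4e-05, or 0.0568 and 0.171 with an estimated correlation. Ifi44, an interferon-induced gene, rose from 5.96 ± 0.445 to 192 ± 23.6 CPM and from 6.36 ± 1.21 to 123 ± 13.0 CPM. Of the chemokines and cytokines, 13 of 18 fell in the small intestine and 15 of 18 in the colon (14 and 15 adjusted over the list alone). For chemokines and cytokines camera gave adjusted p = 0.000527 and 2.51e-06, or 0.128 and 0.0494 with an estimated correlation. Il7 rose from 7.86 ± 1.24 to 152 ± 8.82 CPM and from 17.0 ± 2.17 to 242 ± 42.4 CPM. Of the prostaglandin synthesis list, 5 of 8 fell in the small intestine and 5 of 8 in the colon (5 and 5 adjusted over the list alone). For prostaglandin genes camera gave adjusted p = 0.0178 and 0.00114, or 0.18 and 0.0813 with an estimated correlation. Ptgs2, the inducible cyclooxygenase, fell from 243 ± 50.3 to 23.4 ± 5.86 CPM and from 263 ± 91.1 to 25.6 ± 11.7 CPM. Of the immediate early list, 13 of 16 fell in the colon (13 adjusted over the list alone, camera adjusted p = 1.71e-09, and adjusted p = 0.0667 with an estimated correlation). In the small intestine, 1 rose, 4 fell and 11 did not pass the test (1 and 4 adjusted over the list alone, camera adjusted p = 0.484, and adjusted p = 0.822 with an estimated correlation). Of the immune list, 7 of 14 fell in the colon (12 adjusted over the list alone, camera adjusted p = 0.0798, and adjusted p = 0.688 with an estimated correlation). That count was 0 without CD31- library 3 (0 at an unadjusted p under 0.05 in edgeR), the library with 72.8 CPM of Ptprc. It was 12 without CD31- library 1 or 2 and 1 without CD31+ library 2.

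Relative to CD31- cells, the largest rises in small intestinal CD31+ Rspo3+ cells were Atp12a at least 505-fold, Otoa 849.8-fold with a counting interval of 235 to 7025, Clca2 281-fold, Rbp7 220.3-fold and Fndc8 220.5-fold with a counting interval of 75.0 to 1073. Falls were led by Slco1a4 at least 712-fold, Rtl3 at least 303-fold, Itih2 at least 153-fold and Igkv8-28 1038-fold with a counting interval of 186 to 41047. Colonic rises were led by Ccl21b at least 901-fold, Psg22 at least 184-fold, Pkhd1l1 1662-fold with a counting interval of 298 to 65675, Fam217a 967-fold with a counting interval of 173 to 38208 and Clca2 775-fold with a counting interval of 214 to 6406. Falls in the colon were led by Igkv2-137 634-fold with a counting interval of 175 to 5239.6, Ighv1-39 328-fold, Igkv8-24 114-fold, Igkv12-44 112-fold and Sox8 73.2-fold. Small intestinal Otoa was 524-fold without CD31+ library 1. Without CD31- library 3 the colonic folds were 120.4 for Igkv2-137, 9.15 for Ighv1-39, 45.9 for Igkv8-24 and 7.30 for Igkv12-44. Ccl21b shares reads with Ccl21a, Psg22 with its gene family and the immunoglobulin genes with one another, so their levels are uncertain. Pecam1 rose and Grem1 fell in both tissues, to the levels given above. edgeR called 6950 genes in the small intestine (3211 higher and 3739 lower in CD31+ cells) and 6314 in the colon (2839 higher and 3475 lower). With limma-trend on log2 TPM the balance turned to 4002 higher and 3080 lower in the small intestine and 4069 and 2504 in the colon, and in the small intestine also without CD31- library 2 or 3 (3206 and 3072 or 3418 and 3034). Of the genes edgeR called, 2091 higher and 2499 lower genes were shared, against 479 and 682 for independent lists. Whether the differences between the fractions were unlike in the tissues was not tested. In the small intestine Igkv8-28 lost its call without CD31+ library 1 (adjusted p = 0.0573), with 0.000167 to 0.0573 over its alternatives. In the colon 3 of these calls were lost on leaving out 1 library. Ighv1-39 lost its call without CD31- library 3 (adjusted p = 0.246), with 3.3e-05 to 0.246 over its alternatives. Igkv12-44 lost its call without CD31+ library 1 or 2 (adjusted p = 0.0933 and 0.0966) or CD31- library 3 (adjusted p = 0.294), with 0.00194 to 0.331 over its alternatives. Igkv8-24 lost its call without CD31+ library 1 or 2 (adjusted p = 0.0507 and 0.0512), with 4.35e-05 to 0.173 over its alternatives. A further call was lost by Igkv2-137 with limma voom and limma-trend (adjusted p = 0.355 and 0.0623).

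**Figure D3:**
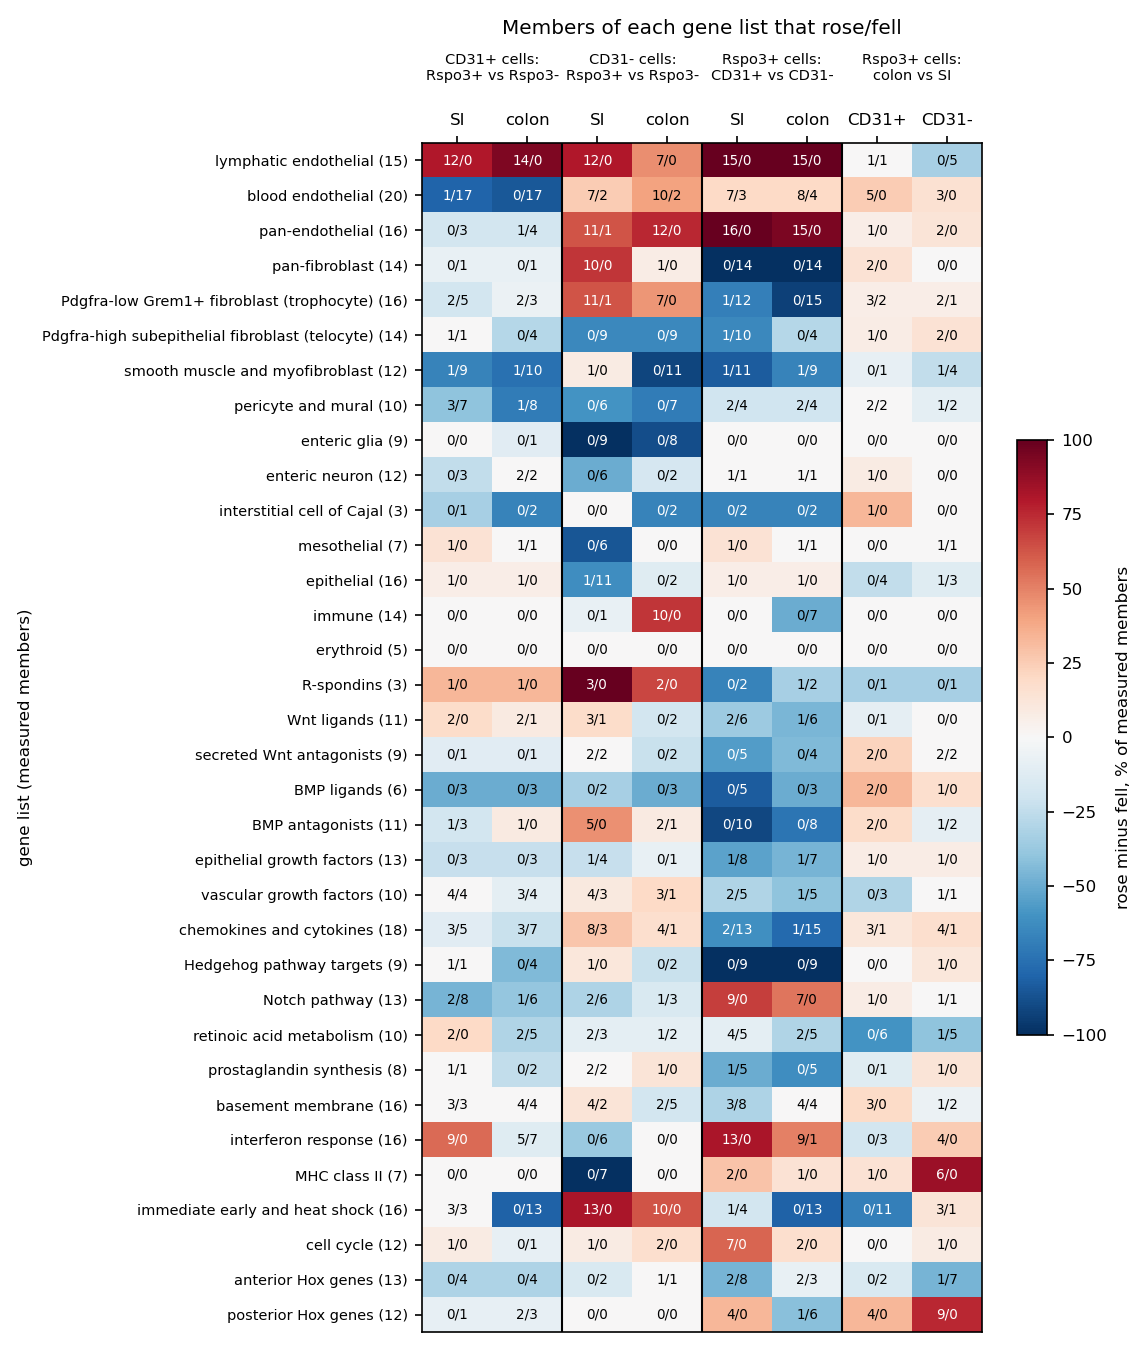
Number of members of each of the 34 gene lists that rose and fell (rose/fell, adjusted p under 0.05 in edgeR) in the 8 comparisons on the horizontal axis, with the measured members in brackets; color shows rose minus fell in percent of measured members (SI, small intestine). The lymphatic list rose in 12 of 15 and 14 of 15 members with the Rspo3 reporter in CD31+ cells, and the pan-fibroblast list fell in 14 of 14 between CD31- and CD31+ cells in both tissues.

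The colon and the small intestine were then compared within each Rspo3+ fraction. Of the posterior Hox genes, which mark position along the gut, 4 of 12 rose in CD31+ cells and 9 of 12 in CD31- cells (8 and 12 adjusted over the list alone). For posterior Hox genes camera gave adjusted p = 5.34e-09 and 4.89e-18, or 0.0112 and 0.000322 with an estimated correlation. In CD31- cells Hoxa10 was at 42.9 ± 10.3 CPM in the colon and 0 in all small intestinal libraries, and Hoxa11 at 22.3 ± 5.73 CPM against 0. In CD31+ cells Hoxa10 was at 4.74 ± 0.229 against 0.143 ± 0.248 CPM (adjusted p = 0.000477). Of the anterior Hox list, 7 of 13 fell in CD31- cells (9 adjusted over the list alone, camera adjusted p = 1.73e-09, and adjusted p = 0.000161 with an estimated correlation). Hoxa5 fell from 40.5 ± 5.70 to 3.06 ± 1.69 CPM (log2 fold change -3.70 ± 0.35 SE, adjusted p = 2.12e-06) and Hoxc4 from 13.4 ± 1.68 to 0.409 ± 0.0294 CPM.

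Of the retinoic acid metabolism list, 6 of 10 fell in CD31+ cells and 5 of 10 in CD31- cells (6 and 7 adjusted over the list alone). For retinoic acid genes camera gave adjusted p = 4.84e-05 and 0.000118, or 0.0907 and 0.0797 with an estimated correlation. The CD31- count was 3 without small intestinal library 1 or 2, 2 without small intestinal library 3, and 3 without colonic library 1 or 3. Cyp26b1, which degrades retinoic acid, fell from 139.5 ± 21.8 to 1.39 ± 1.51 CPM in CD31+ cells. Aldh1a2, which makes it, fell from 228 ± 5.42 to 39.4 ± 9.10 CPM in CD31- cells. The retinaldehyde reductase gene Dhrs3 fell from 359 ± 70.2 to 117 ± 2.85 CPM and from 186 ± 53.7 to 78.5 ± 30.4 CPM. In CD31- cells Dhrs3 lost its call without small intestinal library 3 (adjusted p = 0.0865), with 0.000698 to 0.0875 over its alternatives. Of the immediate early and heat shock list, 11 of 16 fell in CD31+ cells (12 adjusted over the list alone, camera adjusted p = 4.17e-18, and adjusted p = 0.0112 with an estimated correlation). Fos fell from 8988 ± 1308 to 2229 ± 514 CPM.

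Rspo2 in CD31- cells fell from 66.8 ± 3.64 to 6.69 ± 1.65 CPM (adjusted p = 0.0463). Rspo2 lost its call without colonic library 1, 2 or 3 (adjusted p = 0.127, 0.0811 and 0.12) or small intestinal library 1, 2 or 3 (adjusted p = 0.111, 0.116 and 0.12), with 7.63e-07 to 0.127 over its alternatives. The R-spondin list had camera adjusted p = 0.000463, or 0.0156 with an estimated correlation (2 adjusted over the list alone). Rspo3 did not pass the test in either fraction (adjusted p = 0.96 in CD31+ and 0.153 in CD31- cells). In CD31+ cells Wnt2 fell from 278 ± 44.1 to 15.7 ± 3.28 CPM, Il33 fell from 1206 ± 361 to 217 ± 15.9 CPM and Ccl21a rose from 9182 ± 814 to 26946 ± 5827 CPM. In CD31- cells the B-cell chemokine Cxcl13 fell from 657 ± 145 to 21.9 ± 8.19 CPM. The Wnt antagonist Dkk2 fell from 155 ± 17.7 to 3.47 ± 1.36 CPM there, and Bmp6 rose from 56.1 ± 5.94 to 183 ± 27.3 CPM. Rgs5 fell from 262 ± 26.4 to 34.4 ± 9.26 CPM in CD31- cells, and Kcnj8 from 338 ± 24.3 to 76.3 ± 13.1 CPM in CD31+ cells. Fabp1, a fatty acid carrier of small intestinal epithelium, was at 0.458 ± 0.645 against 138 ± 75.5 CPM in CD31+ cells. Of the MHC class II list, 6 of 7 rose in colonic CD31- cells (7 adjusted over the list alone, camera adjusted p = 0.00573, and adjusted p = 0.683 with an estimated correlation). That count was 0 without colonic library 3 (0 at an unadjusted p under 0.05 in edgeR). This library held 1157 CPM of H2-Ab1 and 72.8 CPM of Ptprc. Without small intestinal library 1, 2 or 3 the count was 0 as well (7 at an unadjusted p under 0.05 in edgeR each time).

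The largest rises in colonic CD31+ Rspo3+ cells were Car1 at least 662-fold, Saa1 at least 334-fold, Slc6a14 at least 175-fold, Tspan1 81.8-fold and Sprr2a3 61.6-fold. Falls were led by Adh6a at least 253-fold, Defa24 729-fold with a counting interval of 130.5 to 28856, Fabp1 257-fold, Apoc2 270.4-fold with a counting interval of 92.2 to 1314 and Cyp3a11 239-fold with a counting interval of 81.4 to 1161. In CD31- Rspo3+ cells the largest rises were Car1 at least 2659.5-fold, Mptx1 at least 2116-fold, Hoxa10 at least 920.4-fold, Cd177 at least 593-fold and Retnlb at least 543-fold. The falls there were led by Apoa4 at least 641-fold, Defa23 at least 245-fold, Defa36 at least 182-fold, Adh6a at least 166-fold and Fabp1 1919.7-fold with a counting interval of 531 to 15856. Car1 and Retnlb are known from colonic epithelium, and the Paneth cell defensins (Defa) and Apoa4 from small intestinal epithelium. In CD31- cells most counts of Car1, Mptx1, Cd177 and Retnlb lay in colonic library 3 (means of 111 ± 172, 86.6 ± 148, 24.5 ± 39.8 and 22.5 ± 35.8 CPM), without which the bounds were 216, 23.4, 28.4 and 36.8-fold. Without small intestinal library 2 those of Defa23 and Defa36 were 26.7 and 23.1-fold. Without small intestinal library 3, Apoa4 was at least 313-fold, Adh6a at least 93.3-fold and Fabp1 1033-fold, and Car1 in CD31+ cells was at least 402-fold without colonic library 3. In colonic CD31- library 3, Epcam was at 197 CPM, against 15.3 and 4.20 CPM in the other libraries of its group. Defensin, Saa1, Sprr2a3 and Cyp3a11 reads can be split among near-identical genes, so these levels are uncertain. In CD31+ cells 1209 genes differed between the tissues (539 higher and 670 lower in the colon, edgeR) and in CD31- cells 1337 (689 and 648, turning to 432 and 897 with limma-trend on log2 TPM). Whether the tissue differences were unlike in the fractions was not tested. Both fractions shared 138 higher and 164 lower genes, against 19.5 and 22.8 for independent lists. The CD31+ count was 768 without colonic library 3, and the CD31- count 846, 761 and 745 without small intestinal libraries 1, 2 and 3. Pecam1 did not pass the test in CD31- cells (adjusted p = 0.169). Without colonic library 2 it passed the test (adjusted p = 0.0228, with 0.0228 to 0.918 over its alternatives). In CD31+ cells 4 of these calls were lost on leaving out 1 library. Car1 lost its call without colonic library 1 or 3 (adjusted p = 0.0767 and 0.0889) or small intestinal library 1, 2 or 3 (adjusted p = 0.113, 0.103 and 0.0917), with 1.81e-06 to 0.21 over its alternatives. Slc6a14 lost its call without colonic library 1 or 3 (adjusted p = 0.0713 and 0.0796) or small intestinal library 1, 2 or 3 (adjusted p = 0.112, 0.0999 and 0.0846), with 0.000118 to 0.178 over its alternatives. Sprr2a3 lost its call without small intestinal library 1 (adjusted p = 0.058), with 0.000104 to 0.0938 over its alternatives. Tspan1 lost its call without small intestinal library 1 (adjusted p = 0.0511), with 7.1e-05 to 0.0878 over its alternatives. In CD31- cells 5 were. Car1 lost its call without small intestinal library 1, 2 or 3 (adjusted p = 0.0533, 0.0556 and 0.0577), with 6.72e-09 to 0.166 over its alternatives. Defa23 lost its call without colonic library 1 or 3 (adjusted p = 0.0534 and 0.057), with 1.11e-05 to 0.117 over its alternatives. Defa36 lost its call without colonic library 1, 2 or 3 (adjusted p = 0.103, 0.091 and 0.121) or small intestinal library 2 or 3 (adjusted p = 0.14 and 0.0622), with 0.0012 to 0.14 over its alternatives. Mptx1 lost its call without colonic library 3 (adjusted p = 0.167) or small intestinal library 1, 2 or 3 (adjusted p = 0.123, 0.124 and 0.131), with 1.05e-05 to 0.181 over its alternatives. Retnlb lost its call without small intestinal library 1, 2 or 3 (adjusted p = 0.0682, 0.0685 and 0.0719), with 9.18e-06 to 0.114 over its alternatives. Calls were also lost by Cd177 with limma-trend and only the libraries compared (adjusted p = 0.079 and 0.139) and, in CD31+ cells, by Saa1 with limma voom (adjusted p = 0.0661) and Defa24 with limma voom (adjusted p = 0.283).

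**Figure D4:**
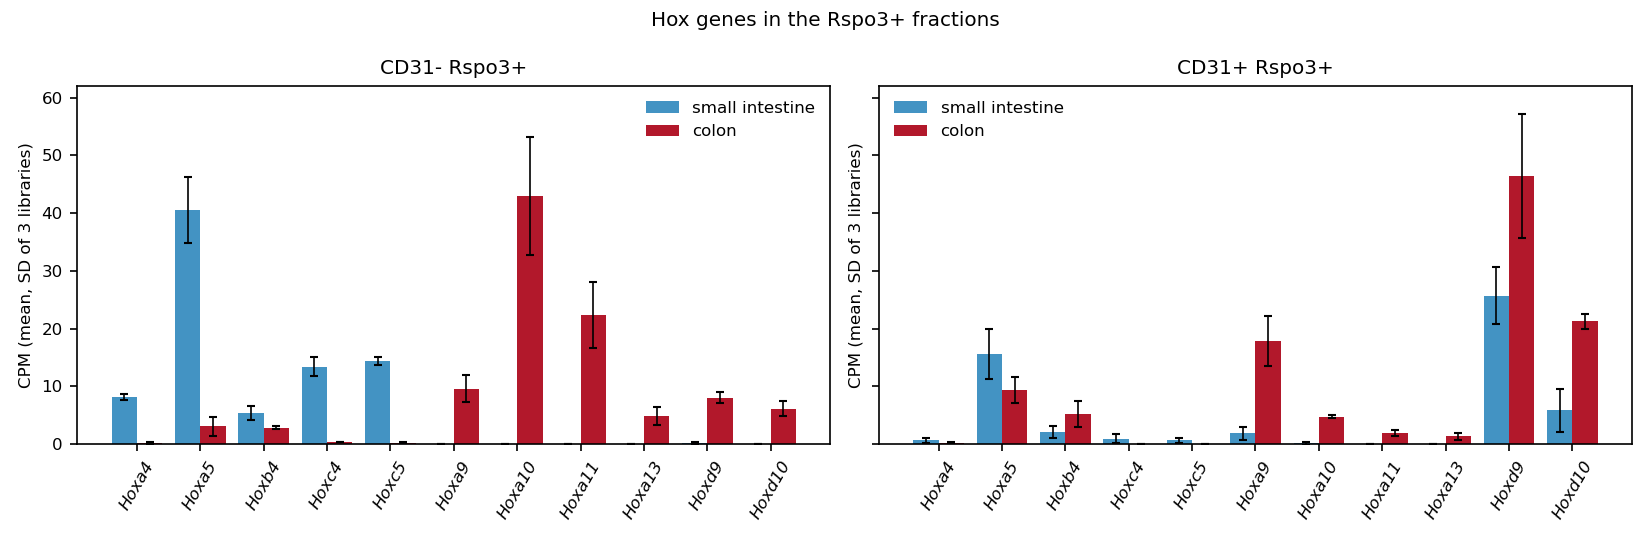
Levels of 11 anterior and posterior Hox genes in CD31- Rspo3+ cells (left) and CD31+ Rspo3+ cells (right) of the small intestine and the colon; bars are means and error bars SD of 3 libraries, in CPM. Hoxa10 reaches 42.9 ± 10.3 CPM in colonic CD31- cells and is at 0 in the small intestinal ones, where Hoxa5 is at 40.5 ± 5.70 CPM.

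Whether the difference between Rspo3+ and Rspo3- cells itself differed between the tissues was tested as an interaction, in log2 (colon minus small intestine). In CD31+ cells 367 genes differed (122 higher and 245 lower in the colon, edgeR). The count was 236 without colonic Rspo3- library 1. Of the immediate early and heat shock list, 10 of 16 were lower in the colon (13 adjusted over the list alone, camera adjusted p = 3.77e-24, and adjusted p = 0.00458 with an estimated correlation). For Fos the difference was -2.45 ± 0.29 SE (adjusted p = 0.000118). Of the interferon response list, 6 of 16 were lower (9 adjusted over the list alone, camera adjusted p = 1.61e-10, and adjusted p = 0.0585 with an estimated correlation). Isg15, an interferon-induced modifier, differed by -2.17 ± 0.29 SE (adjusted p = 0.000412). The actin-capping gene Capg fell in the small intestine (log2 fold change -3.24) and was at -0.41 in the colon, a difference of 2.83 ± 0.26 SE (adjusted p = 1.28e-05). Kcnj8 rose by 3.89 and 0.73 in log2, a difference of -3.17 ± 0.30 SE (adjusted p = 1.28e-05). Nedd9, a scaffold protein, rose by 0.92 in the small intestine and fell by 1.82 in the colon, a difference of -2.73 ± 0.31 SE (adjusted p = 8.39e-05). Pramef8, of a multigene family and so uncertain, differed by -2.42 ± 0.23 SE and Sfxn3 by 2.07 ± 0.22 SE (adjusted p = 1.32e-05 and 5.88e-05).

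In CD31- cells 1597 genes had a different Rspo3 difference in the tissues (935 higher and 662 lower in the colon, edgeR). With limma-trend on log2 TPM this turned to 1069 higher and 2352 lower, and 266 were lower without small intestinal Rspo3+ library 2. The count was 862 without small intestinal Rspo3- library 3, 998 without colonic Rspo3- library 2 and 1037 without colonic Rspo3+ library 3. The 5 genes with the smallest adjusted p, Acsl5, Bpnt1, Cndp2, Slc25a15 and Tle4, fell in the small intestine and did not pass the test in the colon. Acsl5, an enzyme of fatty acid activation, was at -3.29 in the small intestine and 0.12 in the colon, a log2 difference of 3.40 ± 0.24 SE (adjusted p = 1.65e-07). For Bpnt1 the difference was 3.40 ± 0.28 SE, for Cndp2 3.65 ± 0.32 SE, for Slc25a15 3.71 ± 0.31 SE and for Tle4 2.72 ± 0.21 SE (adjusted p = 7.75e-07, 1.4e-06, 7.75e-07 and 3.78e-07). Of the smooth muscle list, 8 of 12 were lower in the colon (8 adjusted over the list alone, camera adjusted p = 9.2e-10, and adjusted p = 0.277 with an estimated correlation). Mylk differed by -2.30 ± 0.28 SE (adjusted p = 4.78e-05). Of the MHC class II list, 7 of 7 were higher (7 adjusted over the list alone, camera adjusted p = 8.11e-05, and adjusted p = 0.385 with an estimated correlation). H2-DMa differed by 3.64 ± 0.77 SE (adjusted p = 0.00564), and by 1.98 without colonic Rspo3+ library 3. That list's count was 2 without colonic Rspo3+ library 3 and 4 without small intestinal Rspo3+ library 1 or colonic Rspo3- library 2. Epcam was at 17.3 ± 9.32 against 783 ± 252 CPM in the small intestine and 72.1 ± 108 against 225 ± 114 CPM in the colon, a difference of 3.86 ± 1.36 SE (adjusted p = 0.0852). It passed the test without colonic Rspo3+ library 1 or 2 (adjusted p = 0.0461 and 0.0195, with 0.0195 to 0.72 over its alternatives), but without colonic Rspo3+ library 3 the difference was 0.95 (adjusted p = 0.72). In the colon alone its fall passed without Rspo3+ library 3 (adjusted p = 0.00305, with 0.00114 to 0.649 over its alternatives). Pecam1 did not pass the interaction test in edgeR (adjusted p = 0.131). It passed with DESeq2 and without colonic Rspo3+ library 2 (adjusted p = 0.0478 and 0.0151, with 0.0151 to 0.538 over its alternatives).

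The last comparison asked which genes accompanied the reporter in both CD31+ and CD31- stroma and in both tissues. In all 4 comparisons 80 genes were higher in Rspo3+ cells, where CD31+ and CD31- lists shared by the tissues would have 29.0 in common if independent, and 108 were lower in all 4, against 32.4. Of the genes changed in both the CD31+ and the CD31- gate, 638 of 1656 went opposite ways in the small intestine and 408 of 867 in the colon. Ranked by their smallest log2 fold change, the first 20 with at least 10 CPM in each Rspo3+ group were Rspo3, Lyve1, Ccl21a, Sema3d, Mmrn1, Nox4, Slc38a4, Lbp, Vldlr, Gm21541, Lrrn4cl, Tgfb3, Dapk1, Fndc1, Il33, Fam124a, Rab3il1, Sirpa, Aebp1 and Frmd6. Their smallest log2 fold changes ran from 3.91 for Rspo3 to 1.23 for Frmd6. Tgfb3, a TGF-beta ligand, had mean levels of 485 and 368 CPM in small intestinal and 229.9 and 192 CPM in colonic CD31- and CD31+ Rspo3+ cells. Fndc1, a fibronectin domain protein, was at 1164 and 401 CPM in small intestinal and 1598 and 506 CPM in colonic CD31- and CD31+ Rspo3+ cells. Lymphatic genes on the list were far lower in the CD31- gate: Lyve1, a hyaluronan receptor, had 53.6 and 5228 CPM in small intestinal and 16.6 and 5659 CPM in colonic CD31- and CD31+ Rspo3+ cells. Of the 80 genes, 66 had both gates within 20-fold of each other in at least 1 tissue, and 14 were under 5% of the CD31+ level in CD31- cells of both tissues. Ccl21a and Gm21541 are near-identical copies and cannot be counted apart. The count of 80 was 52 without colonic CD31- Rspo3+ library 1 and 52 without colonic CD31- Rspo3- library 3. In the colonic CD31- comparison 3 of the calls were lost on leaving out 1 library. Fndc1 lost its call without Rspo3+ library 1 or 2 (adjusted p = 0.0689 and 0.0579) or Rspo3- library 1 or 3 (adjusted p = 0.0901 and 0.0984), with 0.000456 to 0.143 over its alternatives. Frmd6 lost its call without Rspo3+ library 1 (adjusted p = 0.0677) or Rspo3- library 1 or 3 (adjusted p = 0.0519 and 0.0788), with 0.00043 to 0.0861 over its alternatives. Gm21541 lost its call without Rspo3+ library 3 (adjusted p = 0.0667) or Rspo3- library 1, 2 or 3 (adjusted p = 0.0809, 0.0509 and 0.11), with 0.00134 to 0.11 over its alternatives. Calls were also lost by Lyve1 with limma voom (adjusted p = 0.0615), Slc38a4 with only the libraries compared (adjusted p = 0.079) and Fam124a with limma-trend (adjusted p = 0.0928), and in colonic CD31+ cells by Aebp1 with only the libraries compared (adjusted p = 0.0681).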

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

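The tests of carry-over between the Rspo3+ gates in each tissue and the sorting of splits by moved labels were chosen after those results were seen, and so was leaving out a pair of colonic libraries. Other tests in this part were set before their results were seen. The results given first stand apart because the difference between Rspo3+ and Rspo3- cells was not alike in the small intestine and the colon by an interaction test in edgeR. Values are log2 differences, colon minus small intestine. In CD31+ cells 367 genes differed. Among genes named in the text, Gna14 (8.22), Endou (3.54), Capg (2.83), Sfxn3 (2.07) and Apba2 (1.85) were higher in the colon. Atp12a (-7.79), Kcnj8 (-3.17), Nedd9 (-2.73) and Pramef8 (-2.42) were lower, and the immediate early and heat shock list had a median of -1.54. In CD31- cells 1597 genes differed. Pof1b (7.63), Clec2e (6.81), Slc25a15 (3.71), Cndp2 (3.65), Acsl5 (3.40), Bpnt1 (3.40) and Tle4 (2.72) were higher in the colon. Dnaic1 (-3.38), Gm21541 (-3.04), Ccl21a (-2.97) and Vldlr (-1.97) were lower. The values for Gna14, Atp12a, Pof1b, Endou and Clec2e are fitted values that rest on groups at or near 0 counts and are no bounds. Without colonic CD31- Rspo3+ library 3, Clec2e was at 2.03 and Pof1b at 4.72, so that library carries most of the first value and part of the second.

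Calls of the following interactions were lost on leaving out 1 library, with the adjusted p without it in brackets. Apba2 lost its call without colonic Rspo3+ library 1 or 3 (0.0927 and 0.0885), colonic Rspo3- library 2 or 3 (0.0843 and 0.0883), small intestinal Rspo3+ library 1, 2 or 3 (0.0706, 0.102 and 0.0876) or small intestinal Rspo3- library 3 (0.0979), with 0.00305 to 0.128 over its alternatives. Endou lost its call without colonic Rspo3+ library 3 (0.0703) or small intestinal Rspo3+ library 1 or 3 (0.0946 and 0.0564), with 0.00501 to 0.511 over its alternatives. Clec2e lost its call without colonic Rspo3+ library 3 (0.976), colonic Rspo3- library 2 or 3 (0.0776 and 0.0848), small intestinal Rspo3+ library 1 or 2 (0.0829 and 0.0875) or small intestinal Rspo3- library 1, 2 or 3 (0.0502, 0.0517 and 0.111), with 1.38e-06 to 0.978 over its alternatives. Dnaic1 lost its call without colonic Rspo3+ library 1 or 2 (0.0981 and 0.0855), colonic Rspo3- library 1, 2 or 3 (0.062, 0.0845 and 0.0923), small intestinal Rspo3+ library 1 or 3 (0.144 and 0.0941) or small intestinal Rspo3- library 2 or 3 (0.0835 and 0.111), with 0.0001 to 0.144 over its alternatives. Gm21541 lost its call without colonic Rspo3+ library 1 or 2 (0.0687 and 0.0719), colonic Rspo3- library 2 (0.0827), small intestinal Rspo3+ library 2 or 3 (0.118 and 0.0552) or small intestinal Rspo3- library 2 (0.0605), with 0.00156 to 0.141 over its alternatives. Pof1b lost its call without colonic Rspo3+ library 3 (0.211), colonic Rspo3- library 2 or 3 (0.0765 and 0.0561), small intestinal Rspo3+ library 1, 2 or 3 (0.0886, 0.0607 and 0.0742) or small intestinal Rspo3- library 3 (0.0671), with 0.000823 to 0.396 over its alternatives. Vldlr lost its call without colonic Rspo3+ library 1, 2 or 3 (0.0579, 0.0657 and 0.0957), colonic Rspo3- library 1 or 2 (0.0951 and 0.0724), small intestinal Rspo3+ library 1, 2 or 3 (0.066, 0.101 and 0.0932) or small intestinal Rspo3- library 1, 2 or 3 (0.0622, 0.0753 and 0.0888), with 0.00364 to 0.101 over its alternatives. Gna14 in CD31+ cells lost its call with limma-trend (log2 1.37, adjusted p = 0.181).

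For other splits of the interactions the tissue labels were redrawn within each reporter fraction in 100 splits. In CD31+ cells 4 of 100 splits, the real 1 included, gave at least the 367 genes of the real labels, and the highest other count was 602. In CD31- cells 3 of 100 gave at least 1597, with 2412 as the highest other. A first draw of 50 splits had given 3 for either interaction, and the number was raised to 100 only after that was seen. The other splits with as many left the tissue labels of 1 reporter fraction in place, so the tissue difference itself enters their counts, which are no chance values. The 77 and 82 splits that moved labels in both fractions gave at most 10 genes in CD31+ and 0 in CD31- cells, but mixing the tissues within groups adds to the spread, so the splits do not settle whether chance gave the interaction counts. The other comparisons allow 10 splits each, too few for a share under 0.05, and in each of them 1 split, the real 1, gave as many genes. Within CD31+ cells the real counts were 3820 and 4405 in the small intestine and the colon, with 1 and 9 as the highest others. For CD31- cells they were 5796 and 1741, with 1 and 66. For CD31+ against CD31- cells they were 6950 and 6314, with 0 and 0. For colon against small intestine they were 1209 in CD31+ and 1337 in CD31- cells, with 4 and 0.

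Some lymphatic genes were higher in the CD31- Rspo3+ than in the CD31- Rspo3- fraction, at a small share of their CD31+ Rspo3+ level. Lyve1 was at 1.03% in the small intestine and 0.294% in the colon, Ccl21a at 2.13% and 0.398%, and Prox1 at 1.01% and 0.584%. RNA or cells of the CD31+ Rspo3+ fraction, which the CD31 gate was meant to remove, are a candidate explanation and would hold all such genes at 1 share. Over 64 and 59 genes chosen without the CD31- Rspo3+ libraries, the log2 share had an interquartile range of 0.789 and 1.90. List shares covered only members above a minimum level in CD31+ Rspo3+ cells. The small intestine had 11 lymphatic, 14 pan-endothelial and 4 blood endothelial members, and the colon 13, 14 and 5. Their median shares were 1.24%, 1.40% and 1.64% in the small intestine, near 1 share among these members. Colonic medians were 0.584%, 1.90% and 3.27%, and there the explanation stays open. In neither tissue would it cover members far above these. Upper quartiles in the lymphatic list were 11.6% and 18.6%. Highest shares by list were 22.2%, 29.6% and 1.99%, and 51.0%, 82.1% and 1528%. The explanation would not cover some small intestinal members left out either, such as Plvap at 86.9%, Vwf at 70.7% and Pdpn at 47.3%. It does not cover the 80 genes higher in Rspo3+ cells in all 4 comparisons as a whole, since 66 of these had both gates within 20-fold in at least 1 tissue, while for the 14 under 5% in both tissues low expression of their own and carry-over cannot be told apart at these levels. Endothelial cells with little CD31 on their surface remain open and were not tested.

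The CD31- interaction had 935 genes higher in the colon (with limma-trend on log2 TPM 1069 higher and 2352 lower), and the genes it ranked first fell with the reporter in the small intestine, where the Rspo3- libraries held the most Epcam. Library size is argued against: with every library thinned to the lowest total, 1453 genes still differed. Epithelial RNA, which the Epcam gate was meant to remove, may contribute from the small intestinal CD31- Rspo3- libraries and from colonic CD31- Rspo3+ library 3 (Epcam at 197 against 15.3 and 4.20 CPM), without which the median difference of the epithelial list went from 3.80 to 0.83 in log2. In the 6 small intestinal CD31+ libraries, which the interaction does not use, the higher genes had a median correlation of 0.272 with the epithelial list, above the level that 1 in 40 of 1000 random sets of matched level exceeded (0.033) and below the 0.3 set beforehand, but the lower genes, which this RNA would not explain, also exceeded theirs (0.107 against 0.0819), so the test left the part of the small intestinal libraries undecided. A difference between the tissues in the fibroblasts themselves stays open and was not tested.

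In the colon 10 of 14 genes of the immune list were higher in CD31- Rspo3+ cells. Without library 3 of that group 0 rose (1 at an unadjusted p under 0.05 in edgeR), as immune RNA in 1 library would give. The list rose in 3 members without Rspo3- library 1 and in 2 without Rspo3- library 2. The Rspo3+ library 3 held 72.8 CPM of Ptprc and 22999 CPM of Igkc, although the sort gated out CD45+ cells. Whether leukocytes, free RNA or a difference between animals brought this RNA is open and was not tested.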

How the results depend on the processing

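Leaving out a pair of colonic libraries was chosen after the data were seen, and every other alternative was planned. Of 3960 values of 301 named genes and comparisons under the alternatives, 3717 kept their direction and side of the threshold, 220 no longer passed, 23 came to pass and 0 reversed. Counts of genes for Rspo3 in CD31+ cells ran over the alternatives from 2632 to 4462 in the small intestine and 3393 to 5701 in the colon, for Rspo3 in small intestinal CD31- cells from 4291 to 8084, and for CD31 from 6009 to 8415 and 5225 to 7667, all within 1.5 times the reported counts. The colonic CD31- count of 1741 became 3688 with limma voom, 3306 with limma-trend on log2 TPM and 963 with only the libraries compared. With DESeq2 and limma voom, the colon against small intestine counts became 1816 and 1830 in CD31+ cells and 2077 and 2492 in CD31- cells, and the CD31+ interaction 809 and 698. The CD31- interaction rose to 3421 with limma-trend. The 80 shared genes became 139 with limma voom, 33 with limma-trend, 43 with only the libraries compared, 127 without the pair of colonic libraries (CD31- Rspo3+ library 3 and CD31+ Rspo3- library 3) and 36 at an adjusted p under 0.01, a stricter threshold by construction. For the other changes the cause was not tested, except that the fit of only the libraries compared uses fewer samples.

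Leaving out each library in turn gave 1086 to 2331 genes for Rspo3 in colonic CD31- cells, 768 to 923 and 745 to 1414 for the colon in CD31+ and CD31- cells, 236 to 381 and 862 to 1852 for the interactions in CD31+ and CD31- cells, and 52 to 114 shared genes. Without the pair of colonic libraries, Rspo3 gave 4215 genes in colonic CD31+ and 2453 in colonic CD31- cells. With DESeq2 size factors all genes shifted by a median of -0.12 in log2 in the small intestinal CD31- comparison, where 52.9% of the changed genes were higher as reported and 43.3% with these factors. In the CD31- interaction the shift was 0.12, and the share that was higher went from 58.5% to 70.0% (1096 higher and 470 lower), while limma-trend on log2 TPM gave 1069 higher and 2352 lower. Whether more called genes were higher or lower turned under 10 of 12 and 7 of 13 alternatives for Rspo3 in small intestinal and colonic CD31- cells, 3 of 12 and 2 of 13 for CD31, 4 of 13 for the colon in CD31- cells and 1 of 19 for the CD31- interaction, and under none run for Rspo3, the colon or the interaction in CD31+ cells. No paired analysis was possible because the columns of the deposited tables carry no replicate number of the labels. At this depth and with 3 per group, the simulation for the small intestinal CD31+ comparison recovered 34.0% of genes changed 2-fold. It changed 200 of 17234 genes while the data had 3820 calls, so the share missed there is unknown.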

Other observations

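Some secreted Wnt antagonists differed between the Rspo3+ fractions. From CD31- to CD31+ Rspo3+ cells, of the Wnt antagonist list 5 of 9 fell in the small intestine and 4 of 9 in the colon (5 and 5 adjusted over the list alone). For Wnt antagonists camera gave adjusted p = 0.0171 and 0.0198, or 0.221 and 0.231 with an estimated correlation. Dkk3 fell from 652 ± 37.5 to 22.5 ± 6.78 CPM in the small intestine and from 384 ± 83.8 to 47.4 ± 5.34 CPM in the colon.

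Of the pericyte list in colonic CD31- cells, 7 of 10 fell (9 adjusted over the list alone, camera adjusted p = 1.59e-08, and adjusted p = 0.0267 with an estimated correlation), and 4 without Rspo3- library 2. Gm48159, chosen after its values were seen, had the largest minimum log2 fold change of the shared genes (5.58). It lies on chromosome 10 at 29534717 to 29614471 of GRCm38, on the strand opposite to Rspo3 (29452416 to 29535867) and overlapping its end coordinate. Its mean levels were 4.39 and 60.7 CPM in small intestinal and 3.39 and 64.0 CPM in colonic CD31- and CD31+ Rspo3+ cells. Since the library chemistry does not mark strand, reads in the overlap cannot be assigned to either gene.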
